A study of Mus musculus with 2 samples.

How the data were processed

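Single-cell RNA was measured in 2 samples of sorted bone-marrow progenitors, 1 wild-type and 1 lacking Spp1, with 1 library each. The submitters' processing notes name Cell Ranger 1.1 and the mouse build mm10. How reads were filtered, assigned to genes and called as cells beyond that is not given in the sources used here. The authors deposited a matrix of UMI counts (unit: count) with 27998 genes and 7884 barcodes from both libraries together, and its values were whole numbers from 1 to 436 in 11008556 nonzero entries. The libraries were told apart by the suffix of the barcode. No label or file used here ties a suffix to a genotype, so no ratio was given a direction by genotype, and Spp1 counts were not used to set one. Whether the pooled matrix was brought to equal read depth by the authors is not given in the sources used here. Gene positions came from GENCODE mouse release M21 on GRCm38, in which 27645 of the gene identifiers were found. That release is newer than the gene set the counts were made with.

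The gene lists, class markers, filters, comparisons of libraries and most alternatives were fixed before the data were examined. Tests of what lies behind a pattern were chosen once that pattern had been seen. Barcodes with at least 500 genes and under 10% of UMIs from mitochondrial genes were kept, which removed 59 barcodes of library 1 for few genes and 2 of library 2 for mitochondrial UMIs. UMIs were summed per library and scaled to counts per 1000000 UMIs (CPM). In kept cells 15032 genes had a UMI, 10099 had at least 50 UMIs and 1 in each library, and 7526 had at least 200 UMIs. Levels carry exact Poisson 95% intervals, shares exact binomial (Clopper-Pearson) 95% intervals, differences of shares Newcombe intervals, and ratios exact conditional Poisson intervals. For each of the 24 lists the median log2 ratio of members with at least 50 UMIs was set among 10000 random lists of the same size, drawn within 100 ranks of mean expression. The percentile describes a list's position and is not a test. Of the symbols asked for, 3 were missing or not measured under that name (Bim, Mx2 and Ighm). Beside Spp1, the named genes were the 12 with the largest and the 12 with the smallest ratio among genes with at least 200 UMIs whose interval leaves out 1, with sex-linked genes named apart. Of each list they were the 2 to 4 members with the most UMIs or the largest absolute log2 ratio. Per cluster they were taken from the 10 genes with the largest fold over other cells, among genes with a UMI in at least 10% of its cells. Some genes that this rule takes are not reported here.

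Cells of both libraries were clustered together in scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without Spp1, Xist, Y-linked, mitochondrial and ribosomal protein genes were used, with 30 components, 15 neighbours and Leiden resolution 1.0. No batch correction was made, because library and genotype are the same. A cluster was named only from the fixed markers, and the scoring rule was set after the clusters were seen. It asked for 3 markers at 2-fold or more, at least 1 among the top 10 genes and more there than any other class, and no other class with 3 or more additional markers at 2-fold. Ratios within a class were computed where it held at least 200 cells in each library. For co-detection each cell was thinned at random to 2000 UMIs, which left 2444 and 4016 cells and set aside 809 and 554 that were too shallow. The joint share was set against the product of the separate shares, in each library on its own. Scrublet called 1 cell in each library a doublet, too few for its calls to be of use, so no cell was removed for it. Its score ranking served as an alternative, without the 5% of cells with the highest score (163 and 228 cells).

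For shared sequence, the last 300 nucleotides of each gene's longest transcript were taken, with protein-coding transcripts first. Their 50-mers were looked for in the full length of the 141767 transcripts of GENCODE M21. The share that also occurs in another gene was recorded, counting only exact matches on the same strand. Other 3-prime ends of a gene, diverged copies and copies outside this annotation were not covered. Of 7518 searched genes with at least 200 UMIs, 7.93% had any shared 50-mer. How the authors' counting treated reads that match several genes is not given in the sources used here.

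The procedure was tested on simulated data with the depths of these libraries. The interval held the simulated ratio in 95.3% of 7531 genes. Of 50 genes simulated at each fold, the interval left out 1 in 100% at 0.5-fold, 1.5-fold and 2-fold and in 88% at 0.667-fold. A 20-gene list simulated at 1.5-fold reached the 100th percentile, and 2% of 100 unchanged lists lay outside the 2.5th to 97.5th percentile. This covers counting error, not differences between animals or preparations.

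Alternatives were no filter on barcodes, a stricter filter (at least 1000 genes, under 5% mitochondrial UMIs), TMM-scaled library sizes (edgeR 4.0.16 in R 4.3.3), a median-of-ratios size factor, and a library size without mitochondrial and ribosomal protein genes. Others were the mean over cells of CPM, a minimum of 200 UMIs or of 1 UMI per library, Leiden resolutions 0.5 and 1.5, 1000 and 3000 variable genes, and variable genes without the cell cycle lists. Cells were also clustered after thinning, and co-detection was repeated after thinning to 1000 UMIs and without thinning. Figures were drawn with matplotlib 3.10.9.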

Results

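The data were single-cell RNA counts of multipotent progenitors (MPPs), the bone-marrow cells below the haematopoietic stem cell that can still give rise to lymphoid and myeloid lineages. Per the labels, the cells were sorted from mouse bone marrow as lineage-negative, Sca-1-positive, c-kit-positive and CD34-positive, with a gate on Flt3, 20 hours after thioglycollate, an irritant that draws myeloid cells into the peritoneum. The series held 1 C57BL/6 wild-type sample and 1 C57BL/6 sample lacking Spp1, the gene of the secreted matrix protein and cytokine osteopontin. Both were measured with droplet-based 3-prime sequencing, in which each counted molecule (UMI) carries its own tag. The design asked how gene expression of these progenitors differs between the genotypes.

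The counts came as 1 pooled matrix with 2 libraries, told apart by a barcode suffix that no label or file used here ties to a genotype. They are therefore called library 1 and library 2, every ratio is library 2 over library 1, and no direction by genotype is given. Library 1 held 3312 barcodes, of which 3253 were kept, with 10118499 UMIs and a median of 2830 UMIs and 1170 genes per cell. Library 2 held 4572 barcodes, of which 4570 were kept, with 18750468 UMIs and a median of 3836 UMIs and 1534.5 genes per cell. The median share of UMIs from mitochondrial genes was 0.475% and 0.506%. With 1 library per genotype there was no replicate against which to check any difference, so values are given side by side, without tests. The 95% intervals are exact Poisson or binomial (Clopper-Pearson) intervals, or Poisson resampling intervals for list medians, and cover counting error only. Among 10099 genes with at least 50 UMIs, the median log2 ratio was 0.11, and list values are read against it.

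Spp1 was nearly silent in these cells, and almost all of its UMIs lay in library 1. Spp1 (ENSMUSG00000029304) lies on chromosome 5 at 104435118 to 104441050 of GRCm38 (mm10), plus strand, as a protein-coding gene of GENCODE M21. Library 1 had 33 Spp1 UMIs in 30 of 3253 cells (0.922%, 0.623 to 1.31), which is 3.26 counts per 1000000 UMIs (CPM; 2.25 to 4.58). Library 2 had 1 UMI in 1 of 4570 cells (0.0219%, 0.000554 to 0.122), which is 0.0533 CPM (0.00135 to 0.297). The level in library 1 was 61.2 times that in library 2 (10.2 to 2488). After thinning to 2000 UMIs per cell, 11 of 2444 cells of library 1 had a Spp1 UMI, and 0 of 4016 cells of library 2. The binomial interval for library 2 reaches up to 0.0918% of cells. Within library 1, a cluster led by Hbb-bt and Hlf held 10 of the 33 UMIs, in 7 of 601 cells. The lymphoid-primed-like clusters held 1 UMI, in 1 of 615 and 0 of 312 cells, at median depths of 2206 and 3323 UMIs per cell over both libraries. These counts describe the libraries and were not used to assign a genotype.

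Of 11 receptor genes of osteopontin, 6 had at least 50 UMIs, and as a list these had like levels in both libraries. Their log2 ratios ran from -0.37 to 0.31, with 2 above the median of all genes and 4 below. The list of Spp1 receptors, made up of Cd44 and integrin subunits, had a median log2 ratio of 0.0094 (-0.13 to 0.22) over 6 measured members, at the 17.2th percentile of random lists matched on expression. Cd44, the hyaluronan receptor, was at 51.2 and 63.5 CPM (log2 ratio 0.31, 0.16 to 0.46), and Itga4, the alpha-4 integrin of progenitor homing, at 38.3 and 44.3 CPM (0.21, 0.033 to 0.39).

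Genes of G2 phase and mitosis were higher in library 2, all 24 of 24 above the median of all genes. Their median log2 ratio was 0.79 (0.74 to 0.85), at the 100th percentile of 10000 matched random lists, and their summed level was 1822.9 CPM in library 1 and 3040.7 CPM in library 2. Ccnb1, the cyclin that drives entry into mitosis, had a log2 ratio of 1.04 (0.89 to 1.20), and Aurka, a kinase of the spindle poles, 1.02 (0.83 to 1.21). Top2a, which untangles DNA before chromosomes separate, was at 0.46 (0.41 to 0.52), and Birc5, a subunit of the chromosomal passenger complex, at 0.63 (0.57 to 0.70). Genes of S phase had a median of 0.17 (0.13 to 0.22) over 23 members, at the 80.3th percentile, with Dut at 0.61, Rrm1 at 0.41 and Pcna at -0.11. Their position depended on the setting and the cells: the 98.9th percentile with the mean over cells of CPM (0.22), the 16.4th with the stricter filter (0.093), and the 99.8th in the cluster led by Ube2c (0.30). Cells with many mitotic transcripts were also more frequent in library 2. Among cells thinned to 2000 UMIs, 9.57% of library 1 (8.44 to 10.8) and 20.5% of library 2 (19.3 to 21.8) had at least 10 UMIs of the G2 and mitosis list. With a minimum of 5 UMIs the shares were 27.8% and 42.6%, and with a minimum of 20 UMIs 1.23% and 3.26%. Depth went with this result: with 2861 cells per library drawn to the same UMI range, the list exceeded all genes by 0.21 (0.16 to 0.27), against 0.68 over all cells.

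**Figure D1:**
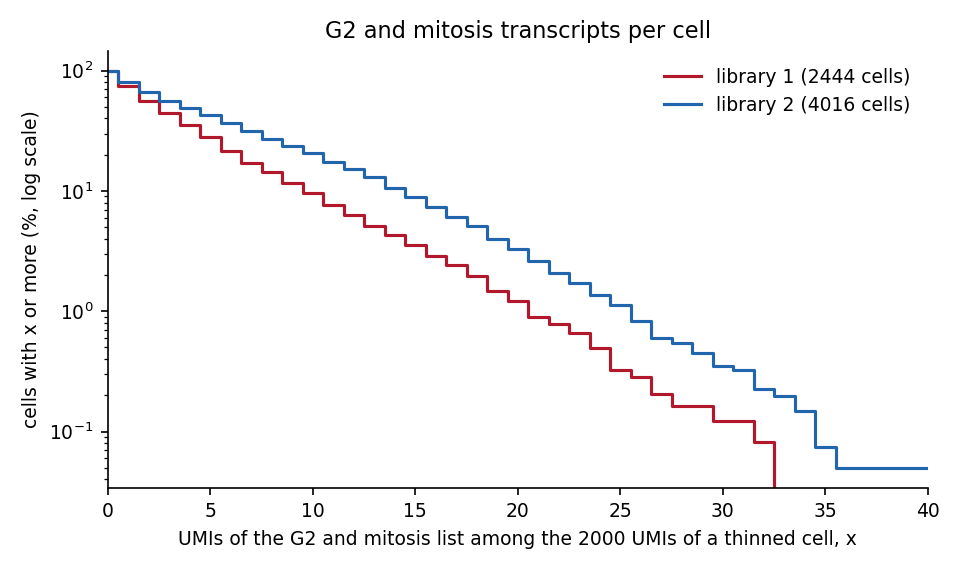
Percentage of cells (log axis) with at least the number of UMIs of the 24 G2 and mitosis genes given on the horizontal axis, after thinning every cell to 2000 UMIs (red line, 2444 cells of library 1; blue line, 4016 cells of library 2). The line of library 2 lies above that of library 1, with 20.5% against 9.57% of cells at 10 UMIs or more.

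Stem and multipotency genes lay lower than other genes in library 2, and lineage-priming genes lay within the middle 95% of random lists over all kept cells. The stem and multipotency list had a median log2 ratio of -0.16 (-0.20 to -0.019), at the 0.06th percentile, with 3 of 15 measured members above the median of all genes. The median was nearer 0 with the stricter filter (-0.045), the mean over cells of CPM (-0.059) and a minimum of 200 UMIs (-0.056), at the 0.95th percentile or lower. Within each cluster of at least 200 cells per library, and within each named class of that size, it lay between the 4.72th and the 41.5th percentile, inside the middle 95%. Mecom, a transcription factor of stem cell maintenance, was at -0.40 (-0.67 to -0.13), and Tal1, required for blood formation, at -0.33 (-0.66 to -0.0042). The sort markers Cd34 and Ly6a, which encodes Sca-1, were at 0.14 and -0.082. Lymphoid priming genes had a median of 0.15 (0.068 to 0.25; 14 members, 75.3th percentile). Dntt, the terminal transferase of early lymphoid cells, was at 0.28, Flt3 at 0.21, Il7r, the interleukin-7 receptor, at 0.34, and the adaptor gene Lax1 at 0.32 with an interval from -0.074 to 0.73. Myeloid priming genes had a median of 0.075 (-0.0068 to 0.18; 18 members, 30.2th percentile), with Plac8 at 0.12 and the granule protease Prtn3 at -0.0044. Irf8, which directs monocyte and dendritic cell fate, was higher in library 2 (117.8 and 166.0 CPM, log2 ratio 0.49, 0.40 to 0.59), and Cebpa, a driver of granulocyte fate, was lower (8.70 and 6.08 CPM, -0.52, -0.93 to -0.098). Megakaryocyte and erythroid priming genes had a median of 0.23 (0.15 to 0.55; 6 members, 91.3th percentile), with carbonic anhydrase 2 (Car2) at 0.23 and the transferrin receptor gene Tfrc at 0.57. With the stricter filter on barcodes lymphoid priming was at the 98.6th percentile (0.26) and megakaryocyte and erythroid priming at the 99.05th (0.40).

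Immediate early genes, which respond to signals or stress within minutes, were lower in library 2. Their median log2 ratio was -0.35 (-0.55 to -0.18), at the 0th percentile, with 12 of 15 measured members below the median of all genes. Fosb was at -1.38, Dusp1, a phosphatase that shuts off kinase signalling, at -0.96, and Fos at -0.51, whereas Myc was at 0.084. The NF-kB and TNF response list was also low over all kept cells, with a median of -0.16 (-0.28 to 0.024) at the 0.21th percentile over 13 members. Its summed level was not lower, at 503.5 and 527.1 CPM. Within clusters of at least 200 cells per library, where at least 5 members were measured, it lay between the 26.9th and the 98.6th percentile. It was thus not low within these clusters. Its members differed: Nfkbiz was at -0.57, whereas the inhibitor gene Nfkbia was at 0.20, Sod2 at 0.18 and the adhesion molecule gene Icam1 at 0.44. Type I interferon response genes did not stand apart (0.049, 0.0032 to 0.13; 22 members, 15.7th percentile). Ifitm3 was at 0.012, Bst2 at 0.041, Usp18 at 0.48 and Oas1a at 2.05, and 21.1% of the 3-prime 50-mers of Oas1a occur in another gene. Toll-like receptor signalling genes had a median of -0.028 (-0.22 to 0.11; 14 members, 7.08th percentile), with Irf3 at 0.14, Irak1 at -0.0073, Traf6 at 0.38 and Irf5 at -0.55.

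Genes that present antigen to T helper cells were lower in library 2, and most of that difference sat in 44 cells. The MHC class II list had a median log2 ratio of -0.41 (-0.87 to -0.26; 9 members, 0th percentile). H2-Aa was at 136.7 and 30.3 CPM (-2.17), H2-Eb1 at 87.2 and 20.7 CPM (-2.07), H2-Ab1 at 192.5 and 62.2 CPM (-1.63), and Cd74, the invariant chain, at 374.3 and 117.9 CPM (-1.67). H2-DMa, which loads peptide onto class II molecules, was at -0.018. A dendritic-like cluster of 44 cells, 42 in library 1 and 2 in library 2, held 80.6% of the H2-Aa UMIs of library 1 and 67.8% of its Cd74 UMIs. Without these cells the list median was -0.070, still at the 0.80th percentile of random lists, and the log2 ratios were -0.081 for H2-Aa, 0.026 for H2-Eb1, -0.070 for H2-Ab1 and -0.20 for Cd74. MHC class I genes, which nearly all cells express, had a median of 0.029 (-0.017 to 0.074; 15 members, 9.58th percentile), with B2m at -0.13, Psmb8 between -0.030 and 0.030 by its interval, H2-D1 at 0.34 and H2-Q4 at 0.33. Both H2-D1 and H2-Q4 share 50-mers with other genes (17.1% and 45.4%).

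**Figure D2:**
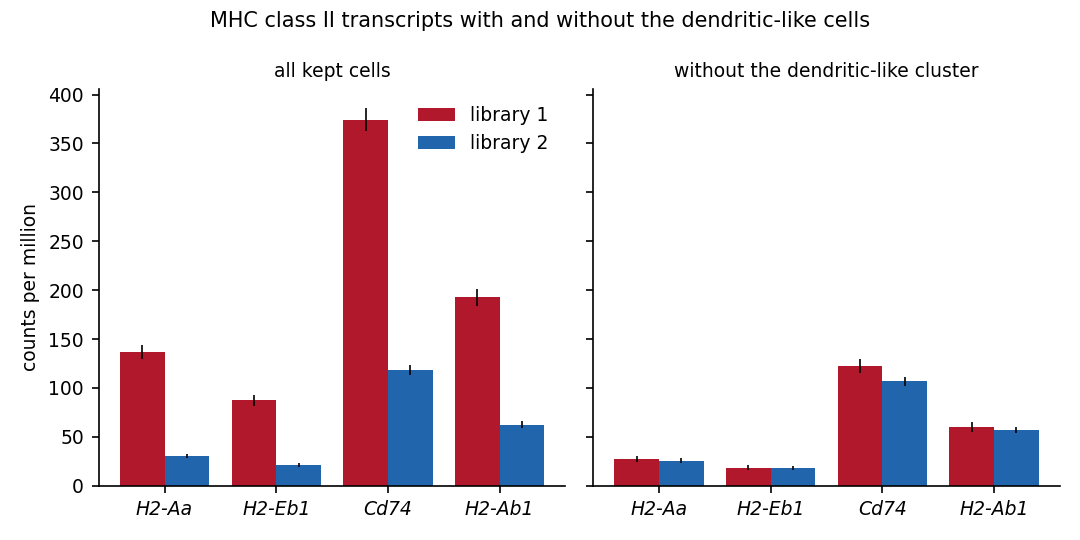
CPM of H2-Aa, H2-Eb1, Cd74 and H2-Ab1 in library 1 (red bars) and library 2 (blue bars), with 95% Poisson intervals, over all kept cells (first panel) and without the 44 dendritic-like cells (second panel). Cd74 was at 374.3 and 117.9 CPM over all cells and at 122.3 and 106.7 CPM without these cells.

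Among genes of cell death, stress and metabolism, p53 targets and heat shock genes lay just outside the middle 95% of random lists. The p53 target list had a median log2 ratio of 0.26 (0.068 to 0.41; 11 members, 97.7th percentile), with the cell cycle inhibitor gene Cdkn1a at 0.72 and Gtse1 at 0.62. The heat shock list had a median of 0.22 (0.14 to 0.23; 12 members, 97.6th percentile), with the chaperone genes Hsp90ab1 at 0.26, Hspa8 at 0.22 (67.3% of its 50-mers shared) and Hsph1 at 0.70, and the stress-inducible Hspa1a at -0.82. Both positions were lost under other settings, the first in 6 and the second in 5 of 12. Pro-apoptotic genes had a median of 0.16 (0.080 to 0.23; 17 members, 76.2th percentile), with Trp53 at 0.25, Bax at 0.13, Cycs at 0.66 and Endog at -0.64. Anti-apoptotic genes had a median of 0.052 (-0.088 to 0.22; 10 members, 22.6th percentile), with Bcl2 at 0.28. ER stress genes had a median of 0.22 (0.14 to 0.33; 16 members, 96.2th percentile), with Calr at 0.14, Hspa5 at 0.38, Hsp90b1 at 0.42 and Sdf2l1 at 0.64. Glycolysis genes had a median of 0.15 (0.12 to 0.21; 15 members, 87.5th percentile), with Ldha at 0.22 and Pkm at 0.16. Pgk1 at 3.23 and Eno1 at 1.72 stood apart from them. Of the 50-mers of Eno1 90.04% occur in another gene, and of those of Pgk1 0%. Migration and chemokine receptor genes had a median of 0.085 (0.032 to 0.25; 12 members, 46.7th percentile), with Selplg at 0.16, Itgb7 at 0.42 and S1pr4 at 0.22.

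Cytosolic ribosomal protein genes, the parts of the translation machinery that hold much of a cell's mRNA, were lower in library 2 (median log2 ratio -0.20, -0.21 to -0.19; 84 members, 0.095th percentile). Their summed level was 384226.7 CPM in library 1 and 342918.4 CPM in library 2, and 68 of 84 members lay below the median of all genes. Rpl32 was at -0.18 and Rps19 at -0.27, whereas Rpl15 was at 2.38 and Rps6 at 2.22. Of the 50-mers of Rpl32 26.7% occur in another gene, and of those of Rps6 83.3%. For Rps19 and for Rpl15, which had the largest ratio of the list, the share was 0%. Mitochondrially encoded genes had a median of 0.20 (0.11 to 0.25; 8 members, 93.6th percentile), with mt-Nd1 at 0.11, mt-Cytb at -0.14 and mt-Co1 at 0.75. All 50-mers of mt-Co1 (100%) occur in another gene; without genes sharing 50-mers the median was -0.0037 (59.2th percentile), and with a minimum of 200 UMIs it was 0.11 (45.8th). The Y-linked genes had like levels in both libraries (median 0.019, -0.18 to 0.16; 4 members, 26.4th percentile), with Eif2s3y at 0.017, Ddx3y at 0.059 and Kdm5d at -0.18, and Xist had 1 and 0 UMIs. Genes within 10 Mb of Spp1 on chromosome 5 had a median of 0.13 (0.067 to 0.16; 93 members, 81.2th percentile), with Rpl5 at -0.47, Pxmp2 at 0.69, Fam69a at 0.61 and Plac8 as above. Scaling by TMM moved the median of all genes from 0.11 to 0.018. This shifted every list alike.

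**Figure D3:**
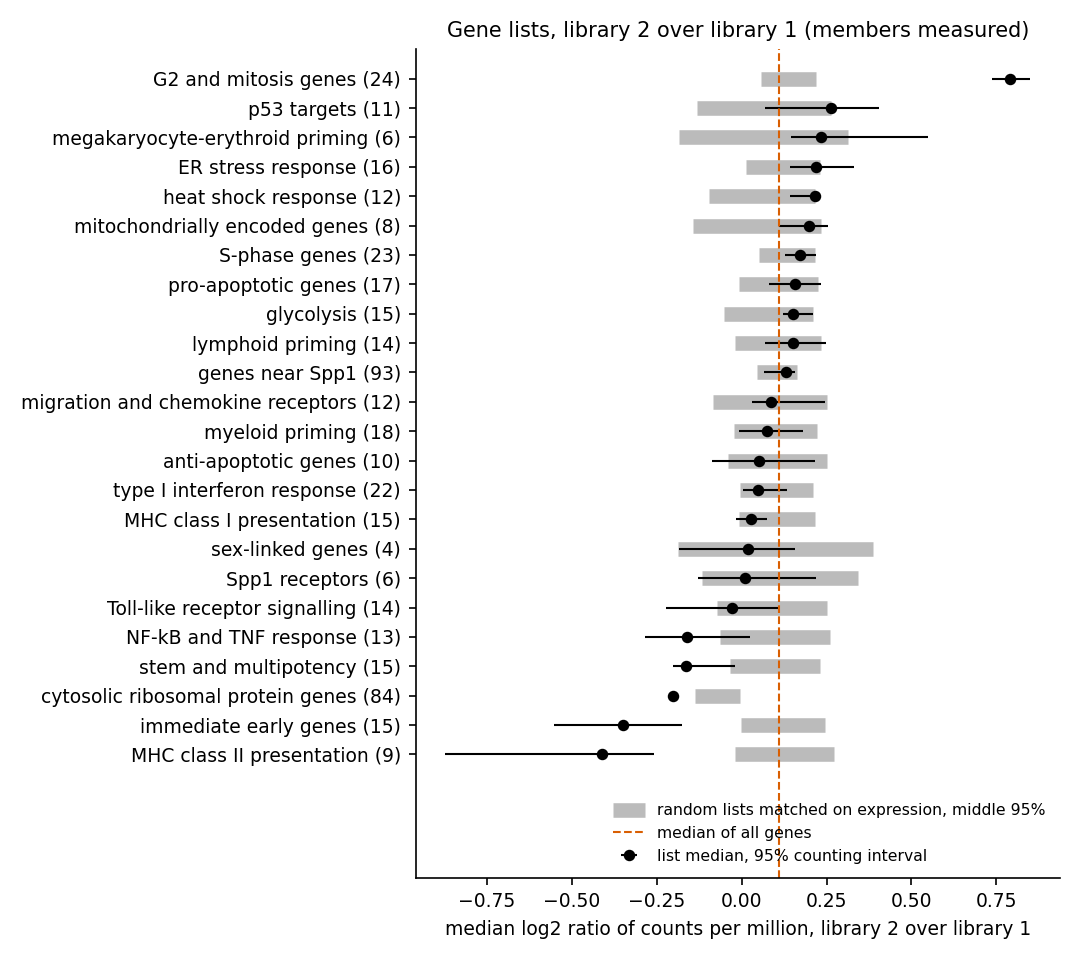
Median log2 ratio of CPM, library 2 over library 1, for each of the 24 gene lists with its 95% counting interval, beside the middle 95% of random lists matched on expression (grey bars) and the median of all genes (dashed line). The G2 and mitosis list, at 0.79, lies farthest above its random lists. The MHC class II list, at -0.41, has the lowest median.

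The single genes farthest apart between the libraries were a mixed set. Among genes with at least 200 UMIs, Wdfy1, an adaptor of endosomal Toll-like receptor signalling, had the lowest ratio (42.3 and 5.87 CPM, log2 ratio -2.85, -3.17 to -2.54). Wdfy1 lies on chromosome 1 at 79702262 to 79776143, and none of its 3-prime 50-mers occur in another gene. H2-Aa (chromosome 17, 34282744 to 34287823), H2-Eb1 (chromosome 17, 34305867 to 34316674), H2-Ab1 (chromosome 17, 34257689 to 34269419) and Cd74 (chromosome 18, 60803848 to 60812652) were among the 12 lowest. So were Fosb (chromosome 7, 19302696 to 19310051) and Id2 (chromosome 12, 25093799 to 25097140). Id2, an inhibitor of E-protein transcription factors, was at 22.9 and 9.0 CPM (-1.36, -1.65 to -1.06). The other 5 were Rps27rt (-1.71), Rpl9-ps6 (-1.34), Gm13139 (-1.33), Rps29 (-1.31) and Gm2000 (-1.30), each with 48.6% to 96.02% of its 50-mers in another gene. At the other end were mt-Nd3, with 1 and 199 UMIs (6.75, 4.25 to 12.06), Gstp1 (3.98), Ndufs5 (3.78), Polr2k (3.57), 1700112E06Rik (3.41), Kpna2 (3.34), Gps1 (3.29), 1810009A15Rik (3.25), Pgk1 (3.23), Ppia (2.78), Akr1b3 (2.61) and Cmss1 (2.53). Of these 12 genes 7 share 50-mers with another gene, from 6.77% of them in Polr2k to 100% in Gstp1. The 5 that do not were 1700112E06Rik, Gps1 (chromosome 11, 120784272 to 120789102), Pgk1 (chromosome X, 106187100 to 106203699), Akr1b3 (chromosome 6, 34302434 to 34317478) and Cmss1 (chromosome 16, 57302000 to 57606864). Pgk1, a glycolytic kinase, was at 6.23 and 58.3 CPM, and Akr1b3, aldose reductase, at 7.71 and 46.99 CPM.

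Clustering of both libraries together gave 10 clusters, of which 4 met the rule for a name. Lymphoid-primed-like cells (2 clusters, 2122 cells) included a cluster led by Il7r, Ly6d and Dntt and a cluster led by the chemokine genes Ccl3 and Ccl4 with Il12a. The Ccl3-led cluster, with 1333 cells, only just met the rule. It had 3 of 12 measured lymphoid-primed markers at 2-fold or more, with 1 among its top 10 genes. Its median fold was 1.52 for lymphoid-primed and 1.29 for stem-like markers. The Il7r-led cluster had 5 of 12 lymphoid-primed and 3 of 4 B-cell markers at 2-fold or more. Together the 2 clusters made up 28.5% of library 1 (26.95 to 30.1) and 26.1% of library 2 (24.9 to 27.4). The difference of -2.35 percentage points (-4.36 to -0.348) turned positive in 6 of 11 other settings. The shares depended on the setting: over those 11 they ranged from 6.33% to 18.1% of library 1 and from 6.23% to 16.9% of library 2, below the intervals given. Granulocyte-monocyte-primed-like cells, led by Elane, Ms4a3, Ctsg and Mpo, made up 6.67% (5.84 to 7.58) and 6.48% (5.78 to 7.23), a difference of -0.194 points (-1.33 to 0.909) that ranged from -7.01 to 4.17 over the settings. These shares ranged from 3.83% to 19.8% of library 1 and from 4.14% to 12.7% of library 2. Within the class, Elane had a UMI in 10.7% of cells and Ms4a3 in 17.3%, against 68.4% for Ctsg and 60.6% for Mpo. At 2-fold or more were 11 of 14 measured granulocyte-monocyte-primed markers, but also 5 of 5 neutrophil and 5 of 9 monocyte and macrophage markers. The median fold was 7.42 for the granulocyte-monocyte-primed and 11.9 for the neutrophil markers. Dendritic-like cells, led by Plbd1, Xcr1 and Batf3, made up 1.29% of library 1 (0.932 to 1.74) and 0.0438% of library 2 (0.0053 to 0.158). This cluster also had 7 of 9 measured monocyte and macrophage markers at 2-fold or more. With 1 library per group, a cluster mostly of 1 library may belong to that library and not to a cell type. The other 6 clusters were led by histone and S-phase genes, by Ube2c and Cenpa, by Ccne2 and Ung, by Hist1h2bc, by Hbb-bt and Hlf, or were of low depth, and were left unnamed. The low-depth cluster, at a median of 1962 UMIs, held 6.09% of library 1 and 1.90% of library 2. Its depth was near that of the named cluster led by Ccl3, at 2206 UMIs. It had 3 of 5 measured erythroid markers at 2-fold or more, but none among its top 10 genes, so no name was given. The difference in depth between the libraries can set its shares, and the cause was not tested. The cluster led by Hbb-bt and Hlf had 2 erythroid markers and 1 stem-like marker among its top 10 genes but 9 of 14 stem-like markers at 2-fold or more against 3 erythroid ones, so neither name was given. Sizes of this cluster and of those led by cell cycle genes are not compared, since the genes that lead them differ between the libraries.

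Within the named classes, G2 and mitosis genes lay above all genes in library 2, by amounts that differed between clusters. Their median log2 ratio was 0.57 (0.46 to 0.73) among 927 and 1195 lymphoid-primed-like cells and 0.55 (0.37 to 0.63) among 217 and 296 granulocyte-monocyte-primed-like cells, with 23 members above the median of all genes in each. The lymphoid-primed-like class pools 2 clusters: the one led by Ccl3, with 615 and 718 cells and 250.1 and 281.4 CPM of these genes, was at 0.27 over 6 members (78.99th percentile), and the one led by Il7r, with 312 and 477 cells and 1566.2 and 2021.5 CPM, at 0.39 (99.9th). Part of the class value can thus come from the mix of the 2 clusters. In the 3 clusters that cell cycle genes define, the list was at 0.40 (100th percentile) in the one led by histone and S-phase genes, 0.15 (89.5th) in the one led by Ube2c and 0.13 (54.4th) in the one led by Ccne2 and Ung. Immediate early genes were at -0.41 (-0.51 to -0.055) in lymphoid-primed-like cells and -0.39 (-0.69 to 0.12) in granulocyte-monocyte-primed-like cells, and at Leiden resolution 0.5 the value in the lymphoid-primed-like cells turned to 0.57. Without the cell cycle lists in the variable genes the value in granulocyte-monocyte-primed-like cells was -0.030. By cluster, immediate early genes lay below the median of all genes in 5 of 7: at -0.33 in those led by Ccl3 and by histone and S-phase genes (both 0th percentile), at -0.39 in the granulocyte-monocyte-primed-like one (0.095th), at -0.14 in the one led by Ccne2 and Ung (2.70th) and at -0.017 in the one led by Ube2c (15.7th). They were at 0.15 in the cluster led by Il7r (48.4th) and at 0.21 in the one led by Hbb-bt and Hlf (72.9th), above that median. S-phase genes were at 0.26 in lymphoid-primed-like cells (98.6th percentile), but at 0.17 in each of the 2 clusters pooled there (67.3th and 87.7th), and at 0.059 in granulocyte-monocyte-primed-like cells (29.2th). Lymphoid priming genes were at 0.16 (0.052 to 0.31) in lymphoid-primed-like cells and 0.047 (-0.11 to 0.29) in granulocyte-monocyte-primed-like cells. Myeloid priming genes were at -0.0043 (-0.20 to 0.17) and 0.13 (0.049 to 0.28). Ribosomal protein genes were at -0.18 and -0.16. ER stress genes were at the 99.8th percentile in lymphoid-primed-like cells (0.36) and at the 87.4th percentile in granulocyte-monocyte-primed-like cells (0.17). Of the 2 lymphoid-primed-like clusters, the one led by Ccl3 was at 0.33 (98.8th) and the one led by Il7r at 0.15 (74.3th). Irf8 was at 111.2 and 192.1 CPM in lymphoid-primed-like cells and at 378.1 and 570.03 CPM in granulocyte-monocyte-primed-like cells.

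Lineage transcripts were counted together in single cells of both libraries, lymphoid and stem-associated ones less often than independence would give. Among cells thinned to 2000 UMIs, Dntt was found in 39.4% of library 1 and 43.7% of library 2, and Mpo, the myeloperoxidase gene of granule-forming cells, in 17.4% and 14.9%. Both occurred together in 141 of 2444 and 219 of 4016 cells, which is 0.839 (0.709 to 0.984) and 0.836 (0.731 to 0.9503) of the number expected from the separate shares. Dntt with Hlf, a transcription factor of stem cells, occurred at 0.631 (0.479 to 0.815) and 0.775 (0.640 to 0.929) of expectation. Mpo with Hlf was at 0.827 (0.570 to 1.16) and 0.681 (0.472 to 0.951). Dntt with Elane, neutrophil elastase, was at 0.241 (0.0292 to 0.871; 2 cells) and 0.186 (0.0383 to 0.542; 3 cells). Flt3 with Mpo was at 1.01 (0.816 to 1.22) and 0.928 (0.781 to 1.09).

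Free RNA reaches every droplet. As a rough ceiling for it, the cluster whose share of cells with a UMI had the lowest upper limit was taken. Only clusters with at least 100 thinned cells of a library were used. Thinning shrinks free RNA more in deep cells, so a deep cluster does not bound it in shallow ones. The ceilings of Dntt in library 2 and of Hlf in library 1 came from the granulocyte-monocyte-primed-like cluster, at a median of 5482 UMIs. Among thinned cells this ceiling was 14.9% (11.4 to 19.0) and 21.5% (16.9 to 26.7) for Dntt in libraries 1 and 2, 6.50% (4.21 to 9.52) and 3.88% (2.32 to 6.06) for Mpo, and 1.44% (0.297 to 4.14) and 2.59% (1.30 to 4.58) for Hlf. The shares of Dntt, Mpo and Hlf (9.37% and 8.32%) over each library lay above these intervals. Those of Elane, 0.859% and 0.921%, did not clear its ceiling of 0.175% (0.00444 to 0.974) and 0.242% (0.0294 to 0.873). Free RNA within these ceilings can still add to the joint counts and was not subtracted. Without thinning, Mpo was found in 60.6% of granulocyte-monocyte-primed-like cells, in 6.10% of the cluster led by Hbb-bt and Hlf and in 13.6% of dendritic-like cells, at the median depths given next. Without thinning, Hlf was found in 25.96% of the cluster led by Hbb-bt and Hlf, at a median of 2434 UMIs, in 13.6% of dendritic-like cells, at 3035.5 UMIs, and in 6.24% of granulocyte-monocyte-primed-like cells, at 5482 UMIs. Without thinning, at median depths of 2830 and 3836 UMIs, Dntt was found in 46.8% and 54.1% of cells and Mpo in 21.1% and 23.3%. The Dntt with Mpo ratios were then 0.955 and 0.968, Dntt with Hlf 0.738 and 0.734, Mpo with Hlf 0.904 and 0.773, Dntt with Elane 0.494 and 0.740, and Flt3 with Mpo 1.25 and 1.19. Thinned to 1000 UMIs, Mpo with Hlf was at 0.444 and 0.380, and Dntt with Hlf in library 2 at 0.460.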

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

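The alternatives without the dendritic-like cells, without the low-depth cluster, without genes sharing 50-mers, and with further genes left out of the variable genes (MHC class II, shared 50-mers, and the cell cycle lists for the values within a class) were chosen only after the data were seen; the others were planned. Of 407 values recomputed, 302 stayed within their counting interval, 98 moved beyond it and 7 changed the sign of a difference whose interval left out 0. Values of cells and depth per library, 7 of the 302 and 1 of the 98, were sorted by a fold limit instead of an interval. Counting every value, 51 of the 407 had another sign than the one reported, among them list medians near 0 that a scaling shifts with all genes. The Spp1 levels stayed within their intervals in all 8 recomputed values. The position of the list among random lists stayed on the same side in 12 of 12 alternatives for G2 and mitosis, stem and multipotency, immediate early, MHC class II and ribosomal protein genes, in 11 for NF-kB, in 7 for heat shock and in 6 for p53 targets. Of the lists inside the middle 95%, lymphoid priming, megakaryocyte-erythroid priming, S-phase and mitochondrially encoded genes left it in 1 alternative each (highest percentiles 98.6, 99.05, 98.9 and 99.3) and ER stress in 2 (99.2 at most). No paired analysis was possible because each genotype has 1 sample. Depth limits the rest: library 2 has more UMIs per cell, and 1 library per genotype leaves no measure of spread. The granulocyte-monocyte-primed-like class had 141 cells in library 1 at Leiden resolution 0.5, under the minimum of 200, so it gave no value within the class there. Unless stated, the cause was not tested.

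TMM scaling, the median-of-ratios factor and a library size without mitochondrial and ribosomal protein genes shift all genes by 1 factor. The median of all genes went from 0.11 to 0.018, 0.020 and 0.016. The first 2 scalings bring it near 0 by construction, and the third does not. Ribosomal protein genes, which the third leaves out, summed to 384226.7 CPM in library 1 and 342918.4 CPM in library 2. List medians were then, under the 3 scalings in that order, -0.25, -0.25 and -0.26 for stem and multipotency, 0.060, 0.061 and 0.057 for lymphoid priming, -0.017, -0.016 and -0.020 for myeloid priming and 0.14, 0.14 and 0.14 for megakaryocyte-erythroid priming. The medians were 0.081, 0.082 and 0.079 for S-phase, 0.70, 0.70 and 0.70 for G2 and mitosis, -0.044, -0.042 and -0.046 for type I interferon and 0.066, 0.067 and 0.064 for pro-apoptotic. In the same order they were -0.063, -0.062 and -0.065 for MHC class I, 0.061, 0.062 and 0.058 for glycolysis, 0.13, 0.13 and 0.13 for ER stress and 0.12, 0.13 and 0.12 for heat shock. For 4 further lists they were -0.0070, -0.0055 and -0.0092 for migration and chemokine receptors, 0.11, 0.11 and 0.10 for mitochondrially encoded, -0.30, -0.29 and -0.30 for cytosolic ribosomal protein and 0.038, 0.040 and 0.036 for genes near Spp1. The other 8 lists stayed within their intervals. Within the lymphoid-primed-like class the median-of-ratios factor gave 0.46 for G2 and mitosis, 0.047 for lymphoid priming and -0.52 for immediate early genes, and 0.044 for myeloid priming in the granulocyte-monocyte-primed-like class.

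The stricter filter on barcodes left 2163 cells in library 1 and gave list medians of 0.26 for lymphoid priming, 0.093 for S-phase, 0.65 for G2 and mitosis, 0.17 for type I interferon, -0.25 for MHC class II and -0.19 for cytosolic ribosomal protein; the cause was not tested. Without genes sharing 50-mers, which also took the median of all genes to 0.053, the medians were -0.22 for stem and multipotency, 0.037 for lymphoid priming, 0.72 for G2 and mitosis, -0.016 for type I interferon, -0.057 for MHC class I, -1.04 for MHC class II, 0.093 for glycolysis, 0.028 for migration and chemokine receptors, -0.0037 for mitochondrially encoded and -0.21 for cytosolic ribosomal protein. A minimum of 1 UMI in each library gave 0.11 for megakaryocyte-erythroid priming, 0.10 for mitochondrially encoded, -0.19 for cytosolic ribosomal protein and 0.049 for genes near Spp1, and a minimum of 200 UMIs gave -0.98 for MHC class II and 0.11 for mitochondrially encoded, with more and fewer members by construction. The mean over cells of CPM gave 0.26 for mitochondrially encoded and -0.19 for cytosolic ribosomal protein. Without the dendritic-like cells the MHC class II median was -0.070.

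The difference in the share of lymphoid-primed-like cells changed sign to 0.554 percentage points with no filter, 4.83 with the stricter filter, 0.957 and 0.589 with 1000 and 3000 variable genes, 0.954 at Leiden resolution 0.5 and 0.910 without the cell cycle lists. It moved to -0.322 in thinned cells and to -0.190 without genes sharing 50-mers. The cause was not tested. For granulocyte-monocyte-primed-like cells it moved to 1.35 with no filter, 1.90 and 4.17 with 1000 and 3000 variable genes, -1.70 at Leiden resolution 1.5 and -7.01 in thinned cells. No filter and the stricter filter also gave a stem-like class, with 240 and 654 cells and with 708 and 282 cells. Within lymphoid-primed-like cells, Leiden resolution 0.5 gave 0.40 for G2 and mitosis, 0.047 for lymphoid priming and 0.57, with the sign changed, for immediate early genes. Leaving the cell cycle lists out of the variable genes gave 0.38 for G2 and mitosis and 0.028 for lymphoid priming. These settings draw the class anew, and the cause was not tested further.

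Co-detection ratios depended on depth. Thinned to 1000 UMIs, Dntt with Mpo in library 2 was at 0.700, Dntt with Hlf in library 2 at 0.460, and Mpo with Hlf at 0.444 and 0.380 in libraries 1 and 2. Without thinning, library 2 gave 0.968 for Dntt with Mpo and 0.740 for Dntt with Elane, and Flt3 with Mpo was at 1.25 and 1.19. Without the 5% of cells with the highest Scrublet score, Dntt with Elane in library 1 was at 0, which rests on 2 cells. The cause was not tested.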

Other observations

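The tests of dendritic-like cells as the source of the MHC class II difference and of an equal mix of clusters for the G2 and mitosis genes were chosen only after the result was seen. The other tests below were set after their pattern was seen and before their own results were.

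UMIs of some lineage genes were spread over many cells and those of others lay in few. Prtn3, a granule protease, had a UMI in 85.6% of all kept cells. After thinning it had one in 80.5% and 80.1% of cells of the libraries. In the Il7r-led cluster, the lowest of the larger clusters, it had one in 49.6% (43.2 to 55.97) and 50.8% (45.96 to 55.7) of cells. This rough ceiling for free RNA leaves much of the spread of Prtn3 open to free RNA. Dntt had a UMI in 51.03% of all kept cells, against 9.09% of dendritic-like cells, with 3.36% of its UMIs in its 20 highest cells. Elane had 2070 UMIs in 114 cells, and 94.6% of them lay in 20 cells, 8 of library 1 and 12 of library 2. The neutrophil gene S100a8 was as concentrated, with 92.6% of 528 UMIs in 20 cells, 10 of each library. Ctsg and Mpo lay between, with 25.6% and 21.2% of their UMIs in 20 cells. Dntt reached 2001.2 CPM (1947.4 to 2056.1) in the cluster led by Il7r, against 149.96 CPM (136.9 to 163.98) in the cluster led by Hbb-bt and Hlf. Car2, a gene of erythroid and stem-like cells, went the other way, with 127.4 CPM (114.1 to 141.9) and 777.3 CPM (747.04 to 808.4).

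Irf8 was higher in library 2 in most clusters and highest in the dendritic-like cells, at 1110.4 CPM (957.7 to 1280.4) over both libraries. In the Il7r-led cluster it was at 167.9 and 290.8 CPM, and in the cluster led by Hbb-bt and Hlf at 20.9 and 47.6 CPM. In the cluster led by Ccne2 and Ung it was lower, at 133.9 and 122.8 CPM, as in the low-depth cluster, at 48.2 and 44.04 CPM. Wdfy1 was lower in library 2 in each of the 9 clusters other than the dendritic-like one, for example 39.5 and 6.05 CPM in the histone-led cluster, 39.4 and 5.19 CPM in the Il7r-led cluster and 50.9 and 6.26 CPM in the granulocyte-monocyte-primed-like cluster. Hist1h2bc, a histone gene, was 19.5-fold higher in a cluster of 261 cells than in all others, with a UMI in 70.5% of its cells, 143 of them in library 1 and 118 in library 2.

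G2 and mitosis genes exceeded all genes by 0.68 on the log2 scale in library 2. The excess was 0.62 (0.50 to 0.67) among cells with at least 2 Dntt UMIs. It was 0.66 (0.52 to 0.81) among cells with Hlf and no Dntt and 0.52 (0.46 to 0.61) among cells with Ctsg or Mpo. The shares of these 4 genes over each library lay above the rough ceiling for free RNA, which does not show that each picked cell was primed. The sets were picked without thinning, so their cells depend on depth, and each set can still mix clusters. The excess was present in each set, so different shares of these sets alone do not give it. A different mix of lineage-primed cells was not excluded. Clusters were also drawn without the cell cycle lists. With those of library 2 weighted to their shares in library 1 the excess was 0.41 (0.34 to 0.45). A different mix of these clusters thus does not give the whole excess. One of these clusters still held 5208.9 and 5548.7 CPM of the G2 and mitosis genes, so cell cycle remained in the clusters. The weighting can thus remove a difference in cell cycle itself, and the part it took away cannot be read as a different mix of cell types. In 1 cluster these genes went the other way, with 1901.6 and 1771.3 CPM. Exact sequence shared with other genes in the searched part does not give the excess, since the 22 members with no shared 50-mer gave 0.66 (0.61 to 0.72). Diverged copies, copies outside the annotation and other ends of a gene were not searched, so reads shared through them stay open. A difference in UMIs per cell cannot be told apart from a difference in cell cycle: matched on UMIs the excess was 0.21 (0.16 to 0.27), but cells of the cluster led by Ube2c held a median of 5179 UMIs against 3352 over all cells, so that matching on UMIs may also match the phase. Genotype stays open and untested, as do differences between the 2 sorts, since each library is 1 preparation.

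Cd74 and the 3 MHC class II genes were lower in library 2, with log2 ratios from -2.17 to -1.63. Without the dendritic-like cells their median lay at -0.19 (-0.30 to -0.076) relative to all genes, which is in line with these 42 cells of library 1 as the source of most of the difference. The cluster held the same 44 cells when MHC class II genes were left out of the variable genes. Xcr1 and Batf3, genes of cross-presenting dendritic cells, were at 82.2 and 146.9 CPM in it and Cd74 at 16338 CPM, and a gate on lineage-negative, c-kit-positive cells would be meant to leave such cells out. Whether they entered through the sort or differ by genotype was not tested.

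The 12 genes with the highest and the 12 with the lowest ratio shared more 3-prime sequence with other genes than random lists did, with mean shares of 39.9% and 34.3% against medians of 1.39% and 3.75%, both at the 100th percentile. A different assignment of reads between near-copies in the 2 libraries can thus bear on the 7 and 5 genes that share any. Among the 7 the shares were uneven, from 6.77% for Polr2k and 21.5% for Ppia to 100% for Gstp1. Most of the searched 50-mers of Polr2k and Ppia occur in no other gene. A different mix of cells was excluded for the 12 highest as a set, with a median of 3.35 (2.85 to 3.88) among lymphoid-primed-like cells alone. For 8 of the lowest the median there was -1.36 (-1.64 to -1.12), but 5 of these 8 share 50-mers with another gene. That median does not settle single genes such as Fosb and Id2. A different mix was also not excluded for the other 4, Cd74 and the MHC class II genes above, where the dendritic-like cells are a candidate source. For genes with no shared 50-mer, such as Wdfy1, Id2, Pgk1 and Gps1, shared sequence in the searched part is no explanation. Genotype, a strain variant and a difference in preparation or counting between the libraries stay open for them and were not tested.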
